A study of Mus musculus with 12 samples.

How the data were processed

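Total RNA had been extracted with TRIzol and sequenced on a NovaSeq instrument by LC-Bio, per the labels. The submitters' notes named StringTie, edgeR and limma without versions, and the genome build mm10. The aligner was not given in the sources used here. The values used were FPKM as deposited by the authors, 1 column per library, in 2 tables of the same genes. Per the file headers the tables also held the authors' fold change as a ratio, its log2, a p-value and a q-value for CRS versus control and for CRS+IMQ versus IMQ. Per the labels the role of edgeR and limma in these columns was not stated. The deposited FPKM values had a floor of 0.0001 in place of 0, and values at or under it were set to 0 here. Read counts were not used here, so tests on counts and their normalization were not run.

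Genes were placed on GRCm38 (mm10) with GENCODE M21 by identifier. Symbols equaled those of the deposited tables for 96.7 percent of the placed genes, and 260 genes had no position. Where a symbol occurred more than once, the gene with the highest mean was taken for the lists. Fragment totals per library were estimated from the spacing of the lowest FPKM values of genes times their length.

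Each comparison kept genes with at least 1 FPKM in at least 3 of its libraries. A gene could thus be kept through 1 group alone, which favors that group in the counts of members higher or lower. Values were log2(FPKM + 1) and were fitted with limma 3.58.1 (statmod 1.5.0, R 4.3.3) with a mean-variance trend and robust empirical Bayes variances. CRS versus control and CRS+IMQ versus IMQ were fitted on their 6 libraries. IMQ versus control, CRS+IMQ versus CRS and the interaction were fitted on all 12. Control and CRS were in 1 deposited table and IMQ and CRS+IMQ in the other. IMQ versus control and CRS+IMQ versus CRS thus compare across tables, where a difference between the tables cannot be told apart from imiquimod. The p-values were two-sided and adjusted by the Benjamini-Hochberg method over the genes of a comparison, and calls had an adjusted p under 0.05. Counts adjusted over the list alone used the same method over the members of a list. The labels did not state whether the samples came from separate animals. The p-values therefore measure only the spread between samples, which may be technical. With 3 samples against 3 the smallest exact p is 0.1, so the calls rest on the variance model of limma.

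Lists were tested with camera at a correlation between genes of 0.01, again with an estimated correlation, and with fry, for lists with at least 5 tested members. There were 29 lists, fixed before the data were examined: IL-23/IL-17 axis, keratinocyte activation and antimicrobial, cornified envelope, neutrophil, interferon-stimulated, proliferation, glucocorticoid-induced, circadian clock, stress hormone and neuropeptide, immediate early and heat shock, sebaceous, adipocyte, skeletal muscle, anagen hair follicle, melanocyte, T cell, macrophage, dendritic, mast, B and plasma cell, fibroblast, endothelial, Schwann cell, erythroid, eicosanoid, glycolysis, nuclear respiratory chain, mitochondrially encoded, and a sex-linked list used only to check labels. A list of 15 basal keratinocyte genes was added after the data were seen. The files name Il36 genes by their older Il1f symbols. Krt85, Tcrg-C1 and Tcrg-C2 were not matched and not analysed here.

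Genes were named by a rule fixed before the data were examined. It took the 10 largest rises and 10 largest falls that passed, reached a mean of 1 FPKM in the higher group, were not predicted genes and had no overlap between the libraries of the groups. It added up to 4 members of each list with the smallest p, and 17 genes of psoriasis, glucocorticoid response and barrier that were always reported. Folds are ratios of group mean FPKM, and no fold is given against a group listed at 0 throughout.

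The code was tested on simulated libraries with 200 changed genes. False calls were 14.1 percent of the calls in CRS versus control, 16.3 percent in CRS+IMQ versus IMQ, 13.6 percent in CRS+IMQ versus CRS and 25.7 percent for the interaction. In IMQ versus control they were 53.5 percent with all 12 libraries and 13.7 percent with the 2 groups alone. These shares hold for 200 changed genes and do not carry over to the far larger counts of calls in the data. Of genes changed 2-fold, 71 percent were found in CRS versus control and 66 percent in CRS+IMQ versus IMQ. With each stressed group as 1 sample 0 percent of the 2-fold and 0 percent of the 4-fold changes were found in either comparison. A list shifted on purpose had an adjusted p of 6.86e-27 in camera, and 0 of the other lists were called, with 27 lists tested in all. Genes were simulated independently of each other, so this does not show how camera behaves with correlated genes. Alternatives fixed in advance were quantile normalization, other filters and pseudocounts, the replicate number as a block, fits of all 12 libraries or of 2 groups, a 2-fold limit, other list tests and leaving out each library. Median-ratio scaling, the average of each stressed group as 1 sample and the same without the third IMQ library were chosen after the data were seen. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.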

Results

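RNA was sequenced from dorsal skin of C57BL/6J mice on day 29, in 12 libraries that formed 4 groups of 3. The groups were untreated controls, mice under chronic restraint stress (CRS), mice treated with imiquimod (IMQ) and mice given both (CRS+IMQ). Restraint stress confines an animal and raises its glucocorticoid hormones. Imiquimod activates Toll-like receptor 7 and produces a psoriasis-like inflammation of mouse skin. Each library gave FPKM values, and 13248 to 13753 genes per library reached 1 FPKM. Depth, estimated from the steps between the lowest FPKM values, was 19.1 to 21.1 M fragments per library (M, mega). Its group means were 20.45 ± 0.261 M in control, 19.9 ± 0.802 M in CRS, 20.1 ± 0.590 M in IMQ and 20.8 ± 0.279 M in CRS+IMQ (SD, n = 3). Only a limited range of depths was searched. Of the low values used, 28.0 to 31.8 percent per library lay within 0.05 of a whole fragment.

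The labels did not say whether the 3 libraries of a group came from separate animals. Spread was judged on 529 to 651 single-transcript genes per group with at least 500 estimated fragments. The median coefficient of variation between libraries was 19.6 percent in control and 17.05 percent in IMQ, against 6.07 percent in CRS and 3.72 percent in CRS+IMQ. An estimate of the spread beyond counting noise, scaled up from the median squared coefficient, was 23.4, 20.25, 6.62 and 3.32 percent in the same order. Each total is therefore given also with the 3 libraries of each stressed group averaged to 1 sample, a choice made after the data were seen. All spread in that fit comes from the control and IMQ libraries. It found 0 percent of simulated 2-fold and 4-fold changes in CRS versus control and in CRS+IMQ versus IMQ, and 2 and 47 percent in CRS+IMQ versus CRS, so a gene it did not call is not shown to be unchanged. The comparisons, gene lists, thresholds and rule for naming genes were fixed before the data were examined. Gene values are mean ± SD in FPKM over the 3 libraries of a group. Fold changes are differences of log2(FPKM + 1), which understate changes at low values, and folds are ratios of group means, the higher over the lower. Tests were two-sided. For every named gene said to rise or fall between 2 groups, all 3 libraries of 1 group lay above all 3 of the other. Any gene has such a separation in 1 of the 10 divisions of 6 libraries into groups of 3. Lists were tested as sets with camera at a preset correlation between genes, and the adjusted p with an estimated correlation follows that of each called set. Only 5 set calls held with an estimated correlation: interferon-stimulated genes in IMQ versus control, neutrophil genes in CRS+IMQ versus CRS, and the neutrophil, interferon-stimulated and B and plasma cell lists in the interaction. Neutrophil and B and plasma cell genes could enter these fits through the CRS+IMQ libraries alone, which favors higher values there. Where a list has no second count, the count adjusted over the list alone was the same as that over all genes.

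**Figure D1:**
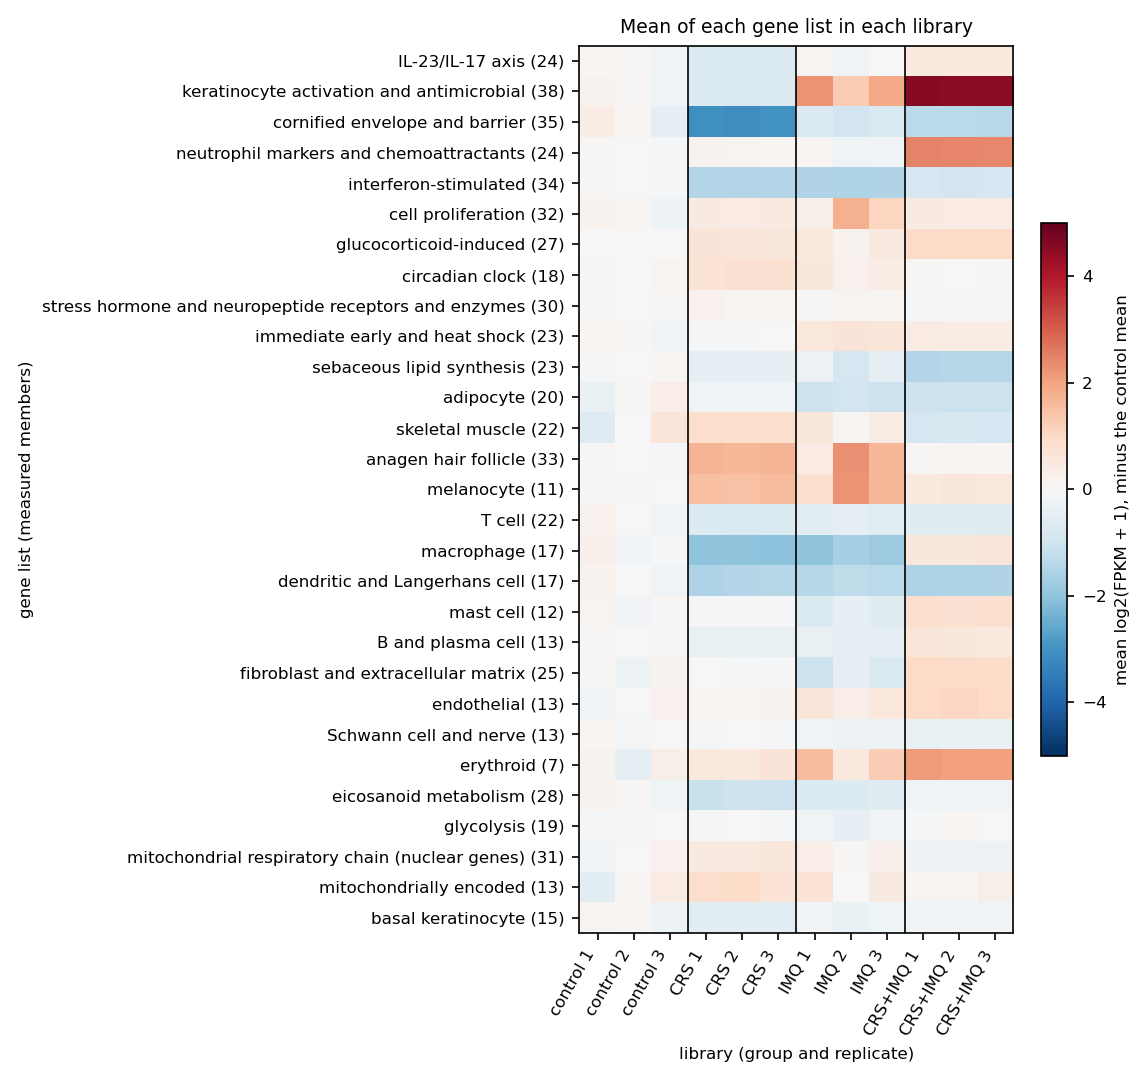
Mean log2(FPKM + 1) of each gene list in each of the 12 libraries, minus the control mean (color), with libraries in columns by group and lists with their measured members on the left. The cornified envelope list averaged -3.08 in CRS relative to control.

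The comparison of CRS with control asked what restraint stress changed in skin that received no imiquimod. Transcripts of the epidermal barrier, of the interferon response and of macrophages and dendritic cells were lower in CRS. Most of those of glucocorticoid response, clock, hair follicle and pigment cells were higher. Of 34 cornified envelope and barrier genes tested, which build the outermost layer of the epidermis, 32 fell and 2 did not pass, with a median log2 change of -3.52 (adjusted p = 5.99e-16, or 0.42 with an estimated correlation). Loricrin (Lor, ENSMUSG00000043165, mm10 chromosome 3, 92080271 to 92083142) fell from 1254 ± 430 to 66.9 ± 5.98, a log2 change of -4.15 (adjusted p = 0.000236). Filaggrin (Flg), which binds keratin filaments, went from 17.9 ± 5.51 to 0.966 ± 0.023 (log2 -3.21, adjusted p = 0.000272). The protease gene Klk5 was 25.1-fold lower and Krt77 24.1-fold lower. Basal keratinocyte genes, a list written after the data were seen, moved less: 11 of 15 fell and 1 rose, with a median of -0.64.

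Glucocorticoid-induced genes, which the hormone's receptor activates directly, had 15 rises and 6 falls among 26 tested (17 and 6 adjusted over the list alone), with a median of 0.63 (adjusted p = 5.82e-05, or 0.0626 with an estimated correlation). Fkbp5 (ENSMUSG00000024222, chromosome 17, 28399094 to 28517527) rose from 3.19 ± 0.331 to 18.4 ± 0.164, a log2 change of 2.21 (adjusted p = 6.97e-05). Zbtb16 rose by 1.87 (adjusted p = 0.000815), Pdk4 was 10.6-fold higher and Tsc22d3, the gene of GILZ, was 2.11-fold higher (adjusted p = 0.0133). Of 18 circadian clock genes 13 rose and 2 fell, with a median of 0.77 (adjusted p = 6.49e-06, or 0.221 with an estimated correlation). Among them Per1 rose from 5.64 ± 0.366 to 24.6 ± 2.01 and Per2 was 22.9-fold higher, while Arntl fell from 4.82 ± 0.318 to 0.787 ± 0.0895. The hour of tissue collection was not taken into account, so a shift in the phase of the clock was not tested. Of 23 immediate early and heat shock genes 6 rose and 9 fell (7 and 10 adjusted over the list alone), among them Nr4a1 with a 10.7-fold rise and Fos with a 3.03-fold rise, and the set did not pass (adjusted p = 0.616). Stress hormone and neuropeptide receptors and enzymes had 5 rises and 2 falls of 16 (set adjusted p = 0.0605).

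Several immune lists fell, while mast cell and neutrophil genes did not pass as sets. All 17 macrophage genes fell, with a median of -2.12 (adjusted p = 1.07e-09, or 0.42 with an estimated correlation). Lysozyme (Lyz2, ENSMUSG00000069516, chromosome 10, 117277331 to 117282321) fell from 1147 ± 207 to 141 ± 3.99 and the macrophage growth factor receptor Csf1r from 60.9 ± 12.4 to 8.03 ± 0.154. All 11 dendritic and Langerhans cell genes fell, including the antigen-presentation gene H2-Aa with a 6.58-fold change (median -2.36, adjusted p = 2.28e-06, or 0.42 with an estimated correlation). Of 33 interferon-stimulated genes 32 fell, with a median of -1.48 (adjusted p = 2.34e-14, or 0.0626 with an estimated correlation). Oasl2 went from 10.7 ± 1.12 to 1.63 ± 0.0234. Of 12 T cell genes 10 fell (median -1.08, adjusted p = 0.000313, or 0.42 with an estimated correlation). Eicosanoid metabolism, which makes prostaglandins and leukotrienes, had 19 falls and 2 rises of 22, and Pla2g2d was 37.0-fold lower (median -1.28, adjusted p = 2.79e-05, or 0.42 with an estimated correlation). The B and plasma cell list had 3 genes tested, too few for a set test, and 2 fell (3 adjusted over the list alone), with Ighm 8.60-fold lower. Mast cell genes had 1 rise and 2 falls of 7 (set adjusted p = 0.859).

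The psoriasis-related lists were divided. Of 11 genes of the IL-23/IL-17 axis, the cytokine pathway of psoriasis, 7 fell and 2 rose (9 and 2 adjusted over the list alone), with a median of -1.17 (adjusted p = 0.0294, or 0.502 with an estimated correlation). The 4 members with the smallest p were IL-36 family genes, and Il36g, which the files name Il1f9, fell from 32.8 ± 9.68 to 1.39 ± 0.483 (adjusted p = 0.000231). Il22 was listed at 0 in all 12 libraries, the group means of Il17a, Il17f and Il23a stayed under 1 FPKM, and Il1b was too low to be tested here. Of 21 keratinocyte activation and antimicrobial genes 12 fell and 6 rose (set adjusted p = 0.278). S100a8 rose from 1.16 ± 0.592 to 11.5 ± 1.81 (adjusted p = 0.000491), S100a9 was 5.45-fold higher and Krt6a 2.72-fold higher (adjusted p = 0.00041), although Krt6a has a close paralog and its values are uncertain. Krt16 fell by 1.91 (adjusted p = 0.0038) and Lcn2 rose by 0.76 (adjusted p = 0.00782), and neither passed with each stressed group as 1 sample (adjusted p = 0.108 and 0.15). Neutrophil markers and chemoattractants had 4 rises and 3 falls of 7 (set adjusted p = 0.293).

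Other tissue components moved with the groups as well. Of 29 anagen hair follicle genes 24 rose and 2 fell (median 1.80, adjusted p = 1.17e-16, or 0.0626 with an estimated correlation). The inner root sheath keratin Krt25 (ENSMUSG00000035831, chromosome 11, 99315516 to 99322951) rose from 0.0249 ± 0.0251 to 44.6 ± 1.15. Of 9 melanocyte genes 8 rose, Mlana by 2.91 (set median 1.84, adjusted p = 1.51e-08, or 0.0626 with an estimated correlation). Of 21 skeletal muscle genes 11 rose and 1 fell (15 and 1 adjusted over the list alone; median 1.07, adjusted p = 2.79e-05, or 0.502 with an estimated correlation). Myh1 was 5.26-fold higher. The muscle list varied within control, with means of -0.63, 0.03 and 0.60 in replicates 1, 2 and 3 against 0.87 in each CRS library. The mitochondrially encoded list had the same order in control, at -0.52, 0.10 and 0.42, against 0.70 to 0.91 in CRS. Cell proliferation had 18 rises of 30 (median 0.53, adjusted p = 5.49e-08, or 0.42 with an estimated correlation). The nuclear genes of the respiratory chain had 22 rises of 31 (25 adjusted over the list alone; median 0.55, adjusted p = 3.02e-09, or 0.42 with an estimated correlation). Mitochondrially encoded genes had 8 rises of 13 (9 adjusted over the list alone; median 0.74, adjusted p = 0.000146, or 0.502 with an estimated correlation). The 5 erythroid genes had a median of 0.79 with no member past the threshold (4 adjusted over the list alone), while the set passed (adjusted p = 0.0257, or 0.502 with an estimated correlation). Endothelial genes had 4 rises and 1 fall of 13 (median 0.23, adjusted p = 0.0413, or 0.648 with an estimated correlation). Sebaceous lipid genes had 11 falls and 1 rise of 21 (13 and 1 adjusted over the list alone; median -0.43, adjusted p = 0.0168, or 0.42 with an estimated correlation). Adipocyte genes (1 rise and 5 falls of 18, adjusted p = 0.859), fibroblast and extracellular matrix genes (7 and 8 of 25, or 9 and 9 adjusted over the list alone, adjusted p = 0.372), Schwann cell and nerve genes (3 and 4 of 12, or 4 and 4 adjusted over the list alone, adjusted p = 0.355) and glycolysis genes (6 and 8 of 19, or 9 and 8 adjusted over the list alone, adjusted p = 0.604) did not pass as sets. Their medians and the directions of their tests differed in sign for the fibroblast list (median -0.09, test higher) and the immediate early list (median -0.07, test higher). For the Schwann cell list the median was 0.23 and the mean -0.04, and for glycolysis the median was 0.30 and the mean -0.06.

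Over all genes, 6086 of 13944 tested passed limma's adjusted threshold of 0.05 in CRS versus control, 2131 higher and 3955 lower. With each stressed group as 1 sample, 793 passed, 188 higher and 605 lower, and 785 of them were among the 6086. Myh1 and Hspb7 did not pass in that fit (adjusted p = 0.0661 and 0.0823), nor did the endothelial set (adjusted p = 0.0671). There the members of the proliferation, skeletal muscle, adipocyte, mast cell, Schwann cell, glycolysis, basal keratinocyte and both mitochondrial lists did not pass singly. The counts were 5 rises for glucocorticoid-induced genes, 5 rises and 2 falls for the clock, 1 rise and 4 falls for the IL-23/IL-17 axis, 1 and 10 for eicosanoid metabolism and 6 falls for dendritic cells. There was 1 fall each among T cell, sebaceous, endothelial and B and plasma cell genes, 3 rises among immediate early genes and 1 each among stress hormone and fibroblast genes, while 28 cornified envelope, 26 interferon-stimulated and 13 macrophage genes fell. The 10 largest rises with no overlap between the libraries of the groups were Krt25, Krt71, H2ac18, Krt73, Krt28, Krt35, Krt27, Ankrd1, Csrp3 and Hspb7, and the 10 largest falls Retnla, Kprp, Asprv1, Krt23, Krt77, Crct1, Lce1m, Klk5, Trex2 and Nccrp1. Retnla (ENSMUSG00000061100, chromosome 16, 48842551 to 48844461) fell from 1524 ± 461 to 54.5 ± 0.298. The share of calls that were higher depended on scaling: 35.015 percent in the values as given, 47.8 percent with median-ratio scaling and 56.2 percent with quantile normalization, which moved the median of all genes from -0.09 to 0.08. The endothelial set was lost without control replicate 1 or 2 or CRS replicate 1 or 2 (medians 0.12, 0.27, 0.25 and 0.21) and with either scaling (0.42 and 0.35), and its median was 0.43 without control replicate 3. Also lost were the sebaceous set without control replicate 3 (-0.40), the erythroid set with either scaling (1.02 and 0.92) and the mitochondrially encoded set with quantile normalization (0.32), and the erythroid median was 0.44 without control replicate 2.

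**Figure D2:**
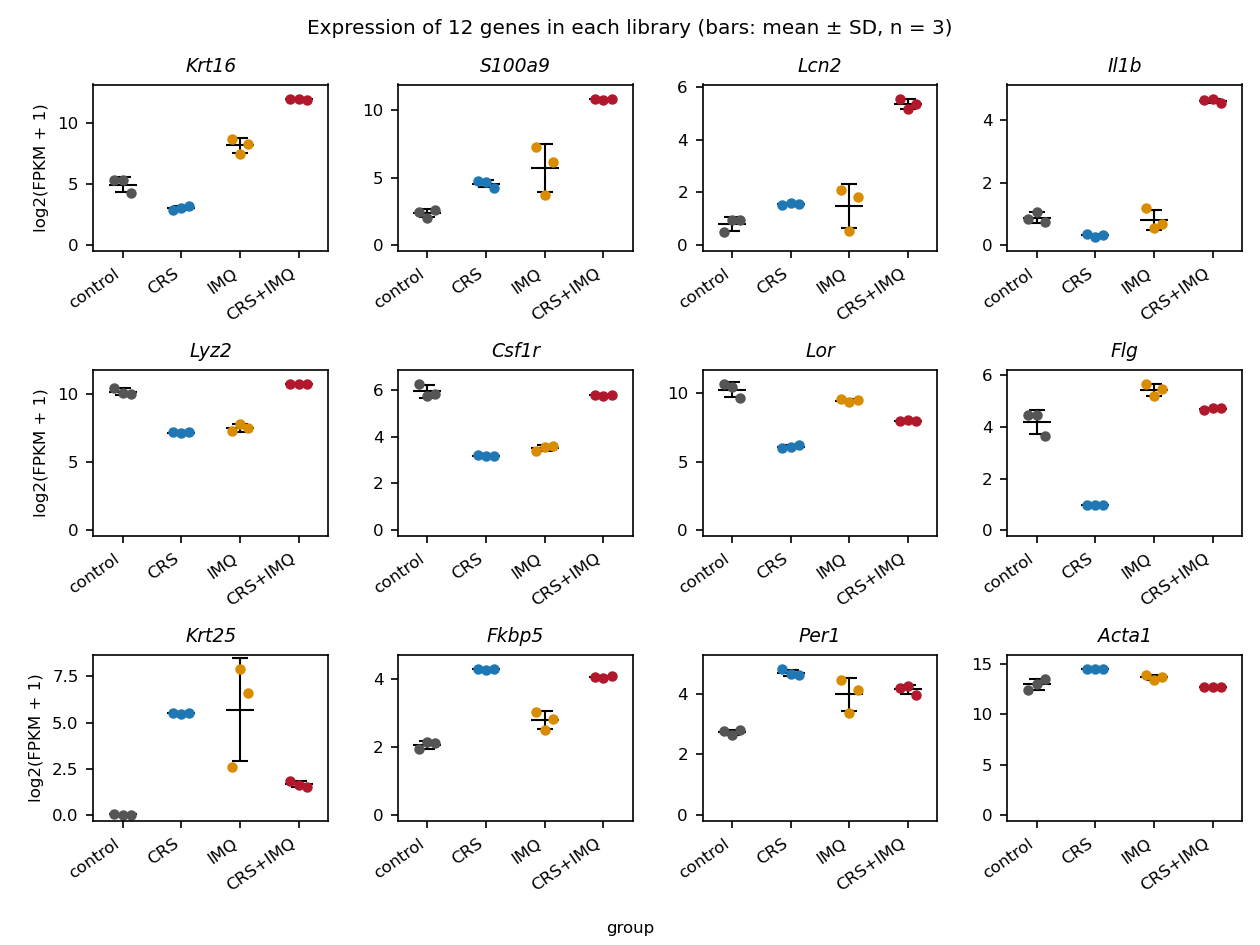
Expression of 12 genes in log2(FPKM + 1) for each library by group, with points for the 3 libraries and bars for mean ± SD. Krt16 averaged 31.8 FPKM in control, 7.26 in CRS, 304 in IMQ and 3921 in CRS+IMQ, and Lyz2 averaged 1147, 141, 182 and 1657 in the same order.

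The comparison of CRS+IMQ with IMQ asked how stress changed skin treated with imiquimod. Keratinocyte activation, neutrophil, macrophage and matrix transcripts were higher in CRS+IMQ, and muscle, sebaceous and hair follicle transcripts were lower. Of 36 keratinocyte activation and antimicrobial genes 33 rose (34 adjusted over the list alone), with a median log2 change of 2.62 (adjusted p = 5.39e-18, or 0.288 with an estimated correlation). The hyperproliferation keratin Krt16 (ENSMUSG00000053797, chromosome 11, 100246091 to 100248902) rose from 304 ± 118 to 3921 ± 64.3, a change of 3.77 (adjusted p = 0.000304). Krt6a, with its paralog unresolved, went from 127 ± 40.9 to 2297 ± 16.6 (log2 4.22, adjusted p = 0.000105). S100a9 (ENSMUSG00000056071, chromosome 3, 90692632 to 90695721), an antimicrobial protein of neutrophils and keratinocytes, rose from 78.4 ± 70.9 to 1769 ± 33.3 (log2 5.07, adjusted p = 0.00556), S100a8 by 4.28 (adjusted p = 0.0171) and Lcn2 by 3.87 (adjusted p = 0.000923). None of these last 3 passed with each stressed group as 1 sample (adjusted p = 0.148, 0.239 and 0.0627). S100a8 did not pass without CRS_IMQ replicate 1, 2 or 3, each left out singly (4.26, 4.30 and 4.28).

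All 23 neutrophil markers and chemoattractants rose, with a median of 2.15 (adjusted p = 5.39e-18, or 0.126 with an estimated correlation). Genes could enter the test through the CRS+IMQ libraries alone, and such genes could appear only as rises. In CRS versus control only 7 members of this list were tested. The collagenase gene Mmp8 went from 0.0559 ± 0.0329 to 17.0 ± 0.605, the receptor gene Csf3r was 24.0-fold higher, and Cxcl5 was listed at 0 in the IMQ libraries and averaged 9.73 ± 0.371 in CRS+IMQ. Of 13 IL-23/IL-17 axis genes 8 rose and 2 fell (9 and 2 adjusted over the list alone; median 0.84, adjusted p = 0.00088, or 0.398 with an estimated correlation). The group means of Il17a, Il17f, Il22 and Il23a themselves stayed under 1 FPKM. Il1b (ENSMUSG00000027398, chromosome 2, 129364570 to 129371139) rose from 0.782 ± 0.432 to 23.8 ± 1.1 (log2 3.83, adjusted p = 4.49e-05), Il24 was 65.3-fold and Il19 20.7-fold higher, and Il6 reached 1.20 ± 0.00601. Il1f9 rose by 0.72 (adjusted p = 0.0142), and its call was lost without CRS_IMQ replicate 1 or 3 (0.69 and 0.73) and with each stressed group as 1 sample (adjusted p = 0.236). Of 17 macrophage genes 16 rose (median 2.60, adjusted p = 7.09e-14, or 0.126 with an estimated correlation), among them Cd68 from 17.8 ± 0.401 to 122 ± 2.24 and Csf1r with a 5.10-fold change. Of 29 interferon-stimulated genes 24 rose (26 adjusted over the list alone; median 0.62, adjusted p = 8.07e-10, or 0.0536 with an estimated correlation), including Ifi27l2a with a 3.31-fold change. Of 9 mast cell genes 8 rose, including Cpa3 with a 10.9-fold change (median 1.51, adjusted p = 3.74e-06, or 0.288 with an estimated correlation). Of 5 B and plasma cell genes 4 rose (5 adjusted over the list alone; median 1.85, adjusted p = 0.000494, or 0.126 with an estimated correlation), although immunoglobulin genes share sequence and are uncertain. T cell genes had 1 rise and 4 falls of 6 (set adjusted p = 0.268), and dendritic and Langerhans cell genes 1 rise and 4 falls of 9 (1 and 5 adjusted over the list alone, set adjusted p = 0.0775).

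Of 25 fibroblast and extracellular matrix genes 23 rose (24 adjusted over the list alone; median 1.76, adjusted p = 3.36e-13, or 0.296 with an estimated correlation). The matrix gene Thbs2 went from 4.52 ± 0.349 to 52.6 ± 1.37. Eicosanoid metabolism had 13 rises and 2 falls of 25 (13 and 3 adjusted over the list alone; median 0.39, adjusted p = 0.000649, or 0.126 with an estimated correlation), with the prostaglandin synthases Ptges 3.13-fold and Ptgs2 16.4-fold higher and the lipoxygenase Alox12e 6.86-fold lower. Endothelial genes had 9 rises of 13 (median 0.56, adjusted p = 0.000182, or 0.398 with an estimated correlation). Erythroid genes had 3 rises of 5 (5 adjusted over the list alone; median 1.16, adjusted p = 0.0277, or 0.515 with an estimated correlation), with globin genes uncertain as paralogs. Glucocorticoid-induced genes had 11 rises and 2 falls of 27 (13 and 3 adjusted over the list alone; median 0.51, adjusted p = 0.000649, or 0.398 with an estimated correlation). Fkbp5 rose from 5.96 ± 1.26 to 15.5 ± 0.294 (log2 1.26, adjusted p = 0.00123, or 0.0836 with each stressed group as 1 sample) and Anxa1 was 3.18-fold higher. Per1 changed by 0.16 (adjusted p = 0.677), Zbtb16 by 0.10 (adjusted p = 0.794) and Tsc22d3 by 0.51 (adjusted p = 0.248), and none of the 3 passed. Clock genes had 3 rises and 9 falls of 17 (4 and 11 adjusted over the list alone; median -0.52, adjusted p = 0.0394, or 0.515 with an estimated correlation), with Dbp 2.24-fold lower.

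Of 32 cornified envelope genes 14 fell and 6 rose (14 and 7 adjusted over the list alone), with a median of -0.07 and a mean of -0.50 (adjusted p = 0.0334, or 0.654 with an estimated correlation). Lor fell from 697 ± 54.3 to 253 ± 6.81 (log2 -1.46, adjusted p = 9.34e-05) and Flg from 42.9 ± 6.88 to 25.2 ± 0.629 (log2 -0.73, adjusted p = 0.00569, or 0.172 with each stressed group as 1 sample). Basal keratinocyte genes had 6 rises and 3 falls of 15 (median 0.19). Of 21 skeletal muscle genes 19 fell (20 adjusted over the list alone; median -1.15, adjusted p = 1.01e-09, or 0.398 with an estimated correlation), with Pvalb 4.94-fold lower. Hair follicle genes had 10 falls and 2 rises of 18 (13 and 3 adjusted over the list alone; median -2.84, adjusted p = 0.015, or 0.58 with an estimated correlation). Melanocyte genes had 2 falls of 6 (3 adjusted over the list alone, set adjusted p = 0.0604). The hair keratin values of IMQ varied between libraries, with Krt25 at 4.97, 237 and 97.4 FPKM in replicates 1, 2 and 3. Sebaceous genes had 10 falls and 1 rise of 20 (median -0.75, adjusted p = 0.00764, or 0.34 with an estimated correlation). Nuclear genes of the respiratory chain had 24 falls of 31 (26 adjusted over the list alone; median -0.49, adjusted p = 6.00e-08, or 0.443 with an estimated correlation). The 31 proliferation genes did not pass singly, while the set passed as lower (median -0.62, adjusted p = 0.00976, or 0.656 with an estimated correlation). The lists of stress hormone receptors (6 rises and 4 falls of 14, or 6 and 5 adjusted over the list alone, adjusted p = 0.597), immediate early genes (3 and 7 of 23, adjusted p = 0.176), adipocytes (7 and 6 of 18, or 7 and 7 adjusted over the list alone, adjusted p = 0.969), Schwann cells (3 and 5 of 11, or 4 and 5 adjusted over the list alone, adjusted p = 0.737), glycolysis (7 and 4 of 19, or 8 and 4 adjusted over the list alone, adjusted p = 0.176) and mitochondrially encoded genes (median -0.27, adjusted p = 0.148) did not pass as sets.

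In CRS+IMQ versus IMQ 5162 of 13981 genes passed limma's adjusted threshold, 2618 higher and 2544 lower. With each stressed group as 1 sample, 820 passed, 671 higher and 149 lower, and 813 of them were among the 5162. Without the third IMQ library as well, 304 passed, 290 higher and 14 lower. The larger direction depended on scaling, on the fit and on 1 library, with 2831 higher and 3109 lower in a fit of all 12 libraries, 2629 higher and 2958 lower under quantile normalization, 2976 and 2199 under median-ratio scaling and 2687 and 3469 without IMQ replicate 1. In the fit with stressed groups as single samples 21 of 36 keratinocyte activation genes, 10 of 25 fibroblast genes, 2 of 29 interferon-stimulated genes, 6 of 27 glucocorticoid-induced genes and 4 of 13 IL-23/IL-17 axis genes rose. Falls numbered 5 of 21 muscle genes, 2 of 18 hair follicle genes and 1 of 20 sebaceous genes, and the members of the nuclear respiratory chain, endothelial, erythroid, clock, immediate early, Schwann cell and melanocyte lists did not pass singly. The cornified envelope had 1 rise and 12 falls, eicosanoid metabolism 8 and 1, stress hormone genes 2 and 1, T cell and dendritic cell genes 1 rise each, glycolysis 3 rises, basal keratinocyte genes 2 rises and adipocyte genes 1 fall. In that fit Dbp, Krt28, Krt73, Krt35, Krt6b, Serpina3b, Serpina3j, Fa2h, Awat1 and Cyp2g1 did not pass, with adjusted p from 0.0590 in Fa2h to 0.263 in Krt35. Without CRS_IMQ replicate 2 the count was 3427. The 10 largest rises without overlap were Retnlg, Saa3, Sprr2i, Cxcl13, Krt6b, Csta3, Chil3, Sprr2j-ps, S100a9 and Sprr2f, and the 10 largest falls Krt28, Krt73, Krt35, Serpina3b, Serpina3j, Retnla, Lhx2, Fa2h, Awat1 and Cyp2g1. The acute phase gene Saa3 went from 6.47 ± 1.15 to 462 ± 5.76 and the B cell chemoattractant Cxcl13 from 2.76 ± 0.749 to 215 ± 7.66. Members of the Sprr2, Csta and Serpina3 families share sequence, and Sprr2j-ps is a pseudogene, so their values are uncertain. The proliferation set was lost without IMQ replicate 2 (median -0.29), the clock set without IMQ replicate 1 (-0.40) and with either scaling (-0.51 and -0.46), the cornified set without IMQ replicate 1 (0.01) and with the replicate number as a block (adjusted p = 0.0629) and the erythroid set with median-ratio scaling (1.21). Medians also moved for proliferation without IMQ replicate 1 (-0.99) and, without IMQ replicate 2, for the cornified envelope (-0.19), glucocorticoid-induced (0.31) and erythroid (0.74) lists. The melanocyte set passed without IMQ replicate 1 (-1.85) and with the replicate number as a block (adjusted p = 0.026), the mitochondrially encoded set without IMQ replicate 2 (-0.41), and the melanocyte and dendritic sets with median-ratio scaling (-1.26 and -0.35). The falls of Krt35, CRS+IMQ versus IMQ, and of Krt73, CRS+IMQ versus IMQ, were not called without IMQ replicate 3 (-4.19 and -4.60) or without CRS_IMQ replicate 1 (-4.55 and -4.91), 2 (-4.64 and -5.02) or 3 (-4.48 and -4.95).

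**Figure D3:**
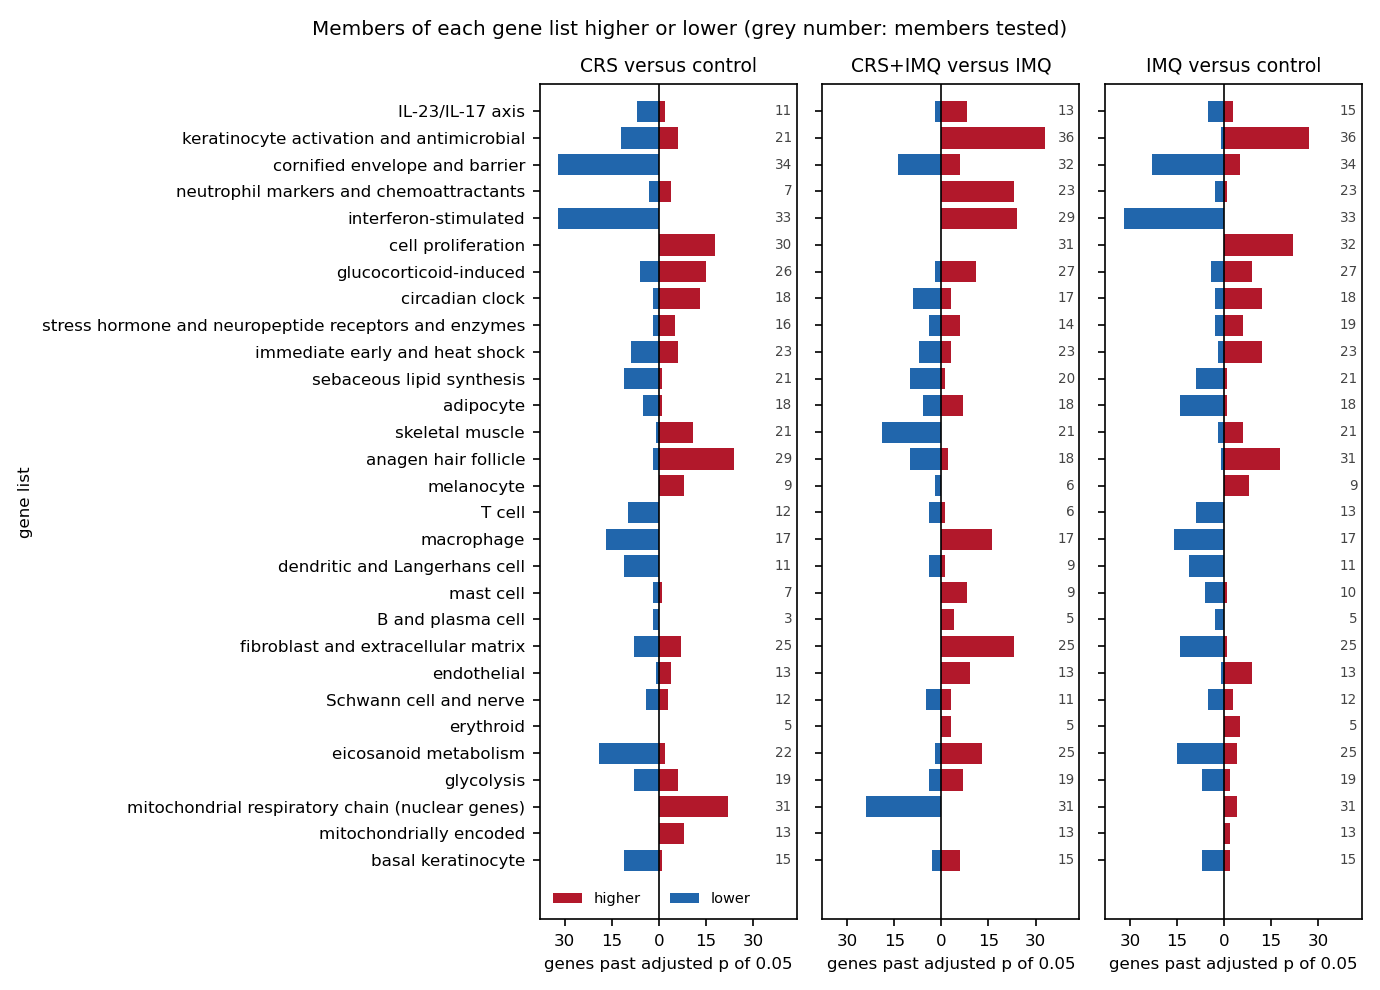
Number of genes of each list higher (right of 0) or lower (left of 0) past an adjusted p of 0.05, with lists in rows, for CRS versus control, CRS+IMQ versus IMQ and IMQ versus control, and the members tested in grey. All 17 macrophage genes fell in CRS versus control, 16 rose in CRS+IMQ versus IMQ and 16 fell in IMQ versus control.

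The comparison of IMQ with control asked what imiquimod left in skin on day 29 without stress. Keratinocyte activation, proliferation and hair follicle transcripts were higher in IMQ, and interferon-stimulated, macrophage, dendritic cell and adipocyte transcripts were lower. Of 36 keratinocyte activation genes 27 rose and 1 fell (median 1.60, adjusted p = 1.56e-13, or 0.282 with an estimated correlation). The cornified envelope gene Rptn, outside that list, rose from 1.26 ± 0.0256 to 78.6 ± 22.1 (log2 5.10, adjusted p = 6.03e-08). Krt16 rose by 3.21 (adjusted p = 3.15e-05), Krt6a by 1.27 (adjusted p = 0.000866), S100a8 by 4.38 (adjusted p = 0.00126) and S100a9 by 3.36 (adjusted p = 0.00282). Lcn2 changed by 0.69 (adjusted p = 0.125), and passed without IMQ replicate 2 (1.17), while Il1b changed by -0.07 (adjusted p = 0.742). Il1f9, whose libraries overlapped between the groups, was at -0.66 (adjusted p = 0.0424, or 0.126 in a fit of the 2 groups alone). Its call was lost without control replicate 1 or 2 or IMQ replicate 2 or 3, each left out singly (-0.48, -0.59, -0.50 and -0.69). Of 15 IL-23/IL-17 axis genes 3 rose and 5 fell (4 and 5 adjusted over the list alone, set adjusted p = 0.887), and of 23 neutrophil genes 1 rose and 3 fell (set adjusted p = 0.887). Cornified envelope genes had 23 falls and 5 rises of 34 (25 and 6 adjusted over the list alone; median -0.71, adjusted p = 7.01e-05, or 0.4552 with an estimated correlation). Krt77 fell from 2459 ± 657 to 13.3 ± 5.33 and Flg rose by 1.25 (adjusted p = 0.000673). Lor fell by 0.78 (adjusted p = 0.0179), and was not called without control replicate 1 or 2 or IMQ replicate 2 (-0.57, -0.68 and -0.72) nor in the 2-group fit (adjusted p = 0.106). Basal keratinocyte genes had 2 rises and 7 falls of 15 (median -0.20).

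Of 33 interferon-stimulated genes 32 fell, with a median of -1.36 (adjusted p = 6.71e-24, and 0.00342 with an estimated correlation). Oasl2 (ENSMUSG00000029561, chromosome 5, 114896936 to 114912234) went from 10.7 ± 1.12 to 1.49 ± 0.282. Of 17 macrophage genes 16 fell (median -2.01, adjusted p = 1.56e-13, or 0.152 with an estimated correlation), including Cd68 with a 6.13-fold change. All 11 dendritic and Langerhans cell genes fell (median -1.84, adjusted p = 9.31e-10, or 0.143 with an estimated correlation). T cell genes had 9 falls of 13 (median -0.84, adjusted p = 0.000143, or 0.3535 with an estimated correlation). Mast cell genes had 6 falls and 1 rise of 10 (median -0.61, adjusted p = 0.0235, or 0.402 with an estimated correlation), and B and plasma cell genes had 3 falls of 5 (set adjusted p = 0.0699). Eicosanoid metabolism had 15 falls and 4 rises of 25 (17 and 4 adjusted over the list alone; median -0.99, adjusted p = 3.31e-05, or 0.3535 with an estimated correlation). Of 18 adipocyte genes 14 fell and 1 rose, including Adipoq from 185 ± 77.9 to 32.2 ± 4.43 (median -1.31, adjusted p = 1.14e-06, or 0.3535 with an estimated correlation). Fibroblast and matrix genes had 14 falls and 1 rise of 25 (16 and 1 adjusted over the list alone; median -0.66, adjusted p = 7.51e-06, or 0.3535 with an estimated correlation). Sebaceous genes had 9 falls and 1 rise of 21 (median -0.55, adjusted p = 0.00656, or 0.3535 with an estimated correlation).

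Immediate early genes had 12 rises and 2 falls of 23, with Fos 10.8-fold higher (median 0.38, adjusted p = 9.18e-05, or 0.143 with an estimated correlation). Proliferation genes had 22 rises of 32 (29 adjusted over the list alone, but 5 with each stressed group as 1 sample; median 1.04, adjusted p = 3.26e-08, or 0.402 with an estimated correlation), and the median was 0.67 without IMQ replicate 2. The list mean relative to control was 0.253, 1.76 and 1.09 in IMQ replicates 1, 2 and 3, and the hair follicle list moved with it at 0.406, 2.29 and 1.65. Among the proliferation genes Mcm5 went from 5.10 ± 1.19 to 19.9 ± 10.3. Hair follicle genes had 18 rises and 1 fall of 31 (10 and 1 with each stressed group as 1 sample; median 1.31, adjusted p = 8.75e-05, or 0.425 with an estimated correlation). The hair follicle median was 0.81 without IMQ replicate 2. Melanocyte genes had 8 rises of 9 (median 1.93, adjusted p = 3.53e-05, or 0.3535 with an estimated correlation). Erythroid genes had 5 rises of 5 (median 1.44, adjusted p = 0.00312, or 0.3535 with an estimated correlation). Endothelial genes had 9 rises and 1 fall of 13 (median 0.64, adjusted p = 0.000143, or 0.3535 with an estimated correlation). Clock genes had 12 rises and 3 falls of 18 (13 and 3 adjusted over the list alone; median 0.51, adjusted p = 0.00771, or 0.3535 with an estimated correlation). Glucocorticoid-induced genes had 9 rises and 4 falls of 27 (10 and 4 adjusted over the list alone; median 0.25, adjusted p = 0.0358, or 0.425 with an estimated correlation), including Fkbp5, which was 1.87-fold higher, and Per1, which was 2.74-fold higher. Zbtb16, whose libraries overlapped, was at 0.77 (adjusted p = 0.0357, or 0.12 in a fit of the 2 groups alone), a call lost without control replicate 1 or 2 or IMQ replicate 1 or 3 (0.65, 0.72, 0.55 and 0.68). Tsc22d3 changed by 0.66 (adjusted p = 0.102) and passed without IMQ replicate 2 (Tsc22d3, IMQ versus control, 1.001). Nuclear genes of the respiratory chain had 4 rises of 31 and mitochondrially encoded genes 2 of 13, which did not pass adjusted over the list alone, while both sets passed (medians 0.23 and 0.39, adjusted p = 0.00092 and 0.0235, or 0.499 and 0.556 with an estimated correlation). The lists of skeletal muscle (6 rises and 2 falls of 21, adjusted p = 0.0754), stress hormone receptors (6 and 3 of 19, or 6 and 4 adjusted over the list alone, adjusted p = 0.693), Schwann cells (3 and 5 of 12, or 3 and 6 adjusted over the list alone, adjusted p = 0.172) and glycolysis (2 and 7 of 19, or 3 and 7 adjusted over the list alone, adjusted p = 0.202) did not pass as sets. The median and the mean differed in sign for the neutrophil list (0.05 and -0.09) and the stress hormone list (-0.01 and 0.16).

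In IMQ versus control 5312 of 14864 genes passed limma's adjusted threshold in the fit of all 12 libraries, 2344 higher and 2968 lower, and 2735 passed in a fit of these 2 groups alone, 854 higher and 1881 lower. In simulated data 53.5 percent of the calls of the first fit were false against 13.7 percent of the calls of the second, so the second count is the safer. Those simulated data had 200 changed genes and 374 calls in the first fit. The false share therefore does not carry over to the 5312 calls. With each stressed group as 1 sample, 2725 passed, 845 higher and 1880 lower, and without the third IMQ library as well 1229, 214 higher and 1015 lower. The larger direction turned under quantile normalization (3131 higher and 2809 lower) and without IMQ replicate 1 (3050 and 2816). The member counts given above are from the first fit. The fit with stressed groups as single samples had 22 rises of 36 for keratinocyte activation, 4 rises and 16 falls of 34 for the cornified envelope, 31 falls of 33 for interferon-stimulated genes and 16 of 17 for macrophages. The counts were 1 rise and 2 falls of 15 for the IL-23/IL-17 axis, 4 and 2 of 27 for glucocorticoid-induced genes, 7 and 3 of 18 for the clock, 8 and 1 of 23 for immediate early genes and 1 and 5 of 21 for sebaceous genes. T cell genes had 6 falls of 13, mast cell genes 4 of 10 and adipocyte and fibroblast genes 11 each, while erythroid genes had 3 rises of 5 and melanocyte genes 6 of 9. Muscle genes had 2 rises and 1 fall, stress hormone genes 2 and 2, glycolysis genes 6 falls and nuclear respiratory chain genes 1 rise, and mitochondrially encoded and basal keratinocyte genes did not pass singly. The 10 largest rises without overlap were Krt25, Krt73, Krt28, Rptn, Krt71, Cstdc5, Krt35, S100a8, Krt27 and Cstdc6, and the 10 largest falls Krt77, Retnla, Mrgprb11-ps, Fcna, Mgl2, Lce1m, Lyz1, Ifitm6, Flg2 and Kctd12, of which Mrgprb11-ps is a pseudogene and the Cstdc, Lce and Lyz1 genes have close paralogs. Sets were lost without single libraries: clock (IMQ replicate 1, median 0.46), glucocorticoid-induced (control replicates 2 and 3 and IMQ replicates 1 and 3, medians 0.20, 0.42, 0.17 and 0.22, and 0.44 without IMQ replicate 2), mast cell (control replicate 3, -0.60), nuclear respiratory chain (IMQ replicate 1, 0.14, with medians of 0.13 and 0.34 without control replicates 1 and 3), mitochondrially encoded (control replicate 1 and IMQ replicate 1, 0.22 and 0.26) and sebaceous (IMQ replicate 2, -0.32). The B and plasma cell set passed without IMQ replicate 1 (-1.07) and with the replicate number as a block (adjusted p = 0.0403), and the muscle set without control replicate 3 or IMQ replicate 2 (0.66 and 0.44), while scaling ended the glucocorticoid-induced call (0.28 with quantile normalization and 0.24 with median-ratio scaling) and quantile normalization the mitochondrially encoded call (0.12).

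The comparison of CRS+IMQ with CRS asked what imiquimod changed in stressed animals. All 36 keratinocyte activation genes rose, with a median of 5.86 (adjusted p = 9.01e-25, or 0.0933 with an estimated correlation). Krt16 went from 7.26 ± 0.755 to 3921 ± 64.3 (log2 8.90, adjusted p = 1.26e-08), Il1b was 98.1-fold higher and S100a9 77.6-fold higher (adjusted p = 2.55e-05). S100a8 was 73.7-fold, Il1f9 23.9-fold, Lcn2 20.7-fold and Krt6a 16.7-fold higher. All 23 neutrophil genes rose (median 1.72, adjusted p = 1.44e-15, and 0.0287 with an estimated correlation). So did all 17 macrophage genes (median 2.59, adjusted p = 1.30e-12, or 0.146 with an estimated correlation), with Lyz2 11.8-fold higher. Neutrophil genes could again enter the test through the CRS+IMQ libraries alone, and such genes could appear only as rises. Cornified envelope genes had 28 rises and 1 fall of 34 (median 1.79, adjusted p = 4.92e-10, or 0.255 with an estimated correlation). Flg was 26.1-fold and Lor 3.78-fold higher while Krt77 was 245-fold lower. IL-23/IL-17 axis genes had 12 rises and 2 falls of 15 (median 1.51, adjusted p = 6.08e-06, or 0.255 with an estimated correlation). Interferon-stimulated genes had 25 rises of 33 (median 0.63, adjusted p = 1.62e-06, or 0.0933 with an estimated correlation). Fibroblast genes had 19 rises of 25, endothelial genes 12 of 13 (13 adjusted over the list alone) and erythroid genes 5 of 5 (adjusted p = 1.62e-06, 3.32e-05 and 0.00921, or 0.255, 0.255 and 0.33 with an estimated correlation). B and plasma cell genes had 5 rises of 5, mast cell genes 7 of 10 (8 adjusted over the list alone) and eicosanoid genes 18 rises and 3 falls of 25 (adjusted p = 0.000283, 0.00333 and 9.08e-05, or 0.0684, 0.255 and 0.255 with an estimated correlation). Immediate early genes had 12 rises and 3 falls of 23 (14 and 3 adjusted over the list alone; adjusted p = 0.0318, or 0.255 with an estimated correlation). This set did not pass with each stressed group as 1 sample, a fit that holds no spread of either group compared.

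Other lists fell in CRS+IMQ relative to CRS. Skeletal muscle genes had 19 falls of 21 (median -1.88, adjusted p = 1.66e-10, or 0.255 with an estimated correlation). Hair follicle genes had 23 falls and 3 rises of 31 (26 and 3 adjusted over the list alone; median -1.46, adjusted p = 1.71e-08, or 0.255 with an estimated correlation). Melanocyte genes had 7 falls of 9 (median -1.23, adjusted p = 0.00155, or 0.33 with an estimated correlation). Clock genes had 12 falls and 2 rises of 18 (13 and 2 adjusted over the list alone; median -0.92, adjusted p = 3.77e-05, or 0.203 with an estimated correlation), with Dbp 3.79-fold lower. Zbtb16 was 2.21-fold lower, and Tsc22d3 changed by 0.18 (adjusted p = 0.654). Fkbp5 changed by -0.23 (adjusted p = 0.14) and Per1 by -0.54 (adjusted p = 0.0649), both of which passed with quantile normalization (-0.40 and -0.71). Nuclear respiratory chain genes had 29 falls of 31 (30 adjusted over the list alone; median -0.79, adjusted p = 1.13e-12, or 0.255 with an estimated correlation). Adipocyte genes had 13 falls of 18 (15 adjusted over the list alone; median -0.91, adjusted p = 1.68e-06, or 0.255 with an estimated correlation). Sebaceous genes had 14 falls of 21 (15 adjusted over the list alone; median -0.68, adjusted p = 5.81e-06, or 0.152 with an estimated correlation). Mitochondrially encoded genes had 8 falls of 13 (9 adjusted over the list alone; median -0.63, adjusted p = 0.000741, or 0.372 with an estimated correlation), a call that quantile normalization ended (-0.31). Schwann cell genes had 5 falls and 1 rise of 12 (median -0.22, adjusted p = 0.024, or 0.255 with an estimated correlation). The lists of glucocorticoid-induced genes (12 rises and 5 falls of 27, or 13 and 7 adjusted over the list alone, adjusted p = 0.142), stress hormone receptors (6 and 8 of 19, adjusted p = 0.341), dendritic cells (1 and 4 of 11, adjusted p = 0.347) and glycolysis (6 and 9 of 19, or 6 and 10 adjusted over the list alone, adjusted p = 0.607) did not pass as sets. T cell genes had 3 rises of 13 (2 adjusted over the list alone, set adjusted p = 0.856), with a median of -0.13 and a mean of 0.12, and the 32 proliferation genes did not pass singly or as a set (adjusted p = 0.35). The glycolysis list had a median of -0.36 and a mean of 0.09. Basal keratinocyte genes had 7 rises and 2 falls of 15 (8 and 2 adjusted over the list alone, median 0.30).

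In CRS+IMQ versus CRS 6718 of 14864 genes passed limma's adjusted threshold, 3991 higher and 2727 lower, and 1111 passed with each stressed group as 1 sample, 930 higher and 181 lower, with 1106 shared. Without the third IMQ library as well, 589 passed, 538 higher and 51 lower. Both groups are single averages in that fit, so its calls carry no measured spread of either group. In that fit rises numbered 17 of 34 cornified envelope genes, 8 of 15 IL-23/IL-17 axis genes, 9 of 25 eicosanoid genes, 4 of 25 fibroblast genes, 4 of 13 endothelial genes, 3 of 10 mast cell genes and 1 of 33 interferon-stimulated genes. Falls numbered 7 of 31 hair follicle genes, 4 of 18 clock genes and 1 each of the muscle, sebaceous and nuclear respiratory chain genes. Members of the adipocyte, melanocyte, erythroid, Schwann cell and mitochondrially encoded lists did not pass singly. In that fit S100a8, S100a9, Lor, Zbtb16, Krt24, Krt25, Krt28, Krt35, Krt71 and Krt73 did not pass, with adjusted p from 0.0512 in S100a9 to 0.393 in Krt71. The 10 largest rises without overlap were Sprr1b, Krt16, Cstdc5, Sprr2d, Sprr2h, Krt6b, Sprr2a2, Sprr2a1, Saa3 and Stfa1, most of them of families with close paralogs, and the 10 largest falls Krt77, Serpina3b, Serpina3j, Krt28, Krt35, Krt73, Krt24, Krt75, Krt25 and Krt71. The share of calls that were higher was 59.4 percent in the values as given and 43.6 percent with quantile normalization, which moved the median of all genes from 0.06 to -0.07.

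The interaction of stress and imiquimod asked whether the effect of stress differed between skin with and without imiquimod, and it compared CRS+IMQ minus IMQ with CRS minus control. Values above 0 mean a more positive effect of stress with imiquimod. The largest differences by list were those of macrophages and keratinocyte activation on the positive side and those of melanocytes, muscle and hair follicle on the negative side. All 17 macrophage genes were past the threshold and positive (median 4.77, adjusted p = 6.83e-14, or 0.143 with an estimated correlation), with Lyz2 at 6.2 (adjusted p = 1.54e-08) and Csf1r at 5.01. Keratinocyte activation genes had 32 of 36 positive (median 3.57, adjusted p = 6.62e-14, or 0.241 with an estimated correlation), with Krt16 at 5.68 (adjusted p = 3.14e-06), Krt6a at 2.78 and Lcn2 at 3.11. S100a9 was at 2.87 (adjusted p = 0.0258), which was not past the threshold without control replicate 1 or 3 or CRS replicate 3 (2.83, 2.76 and 2.71) or with each stressed group as 1 sample (adjusted p = 0.286). S100a8 was at 1.71 (adjusted p = 0.21), which passed without IMQ replicate 1 (2.48). Interferon-stimulated genes had 32 of 33 positive (median 2.05, adjusted p = 7.36e-16, and 0.0139 with an estimated correlation). Relative to control this list's mean was -1.48 to -1.47 in the CRS libraries, -1.53 to -1.50 in IMQ and -0.96 to -0.87 in CRS+IMQ. Every other group thus lay below control, and the fall from control to CRS made up the larger part of this difference. Neutrophil genes had 21 of 23 positive (median 1.63, adjusted p = 3.46e-12, and 0.0342 with an estimated correlation). Their mean relative to control was 0.11 to 0.17 in CRS, -0.21 to 0.08 in IMQ and 2.40 to 2.47 in CRS+IMQ libraries. B and plasma cell genes had 5 of 5 positive (median 2.93, adjusted p = 0.00034, and 0.0488 with an estimated correlation). Genes of both lists could enter the fit through the CRS+IMQ libraries alone, which favors positive differences. Cornified envelope genes had 31 of 34 positive (median 2.37, adjusted p = 1.42e-12, or 0.272 with an estimated correlation), with Lor at 2.69 and Flg at 2.48. Relative to control this list's mean was -3.12 to -3.04 in CRS, -0.94 to -0.72 in IMQ and -1.37 to -1.36 in CRS+IMQ libraries. Stress thus went with a lower mean in both settings, and the positive difference reflects the larger fall without imiquimod. The IL-23/IL-17 axis had 13 positive and 2 negative of 15 (median 1.85, adjusted p = 3.37e-05, or 0.272 with an estimated correlation), with Il1b at 4.39 (adjusted p = 1.07e-07) and Il1f9 at 4.52. Il17a, Il17f, Il22 and Il23a had group means under 1 FPKM throughout.

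Dendritic cell genes had 11 positive of 11, mast cell genes 9 of 10 and T cell genes 8 of 13 (medians 1.70, 1.60 and 0.88, adjusted p = 3.37e-05, 0.000637 and 0.0106, or 0.254, 0.272 and 0.427 with an estimated correlation). Control stood above every other group in the dendritic and T cell lists. Relative to control the dendritic mean was -1.55 to -1.43 in CRS, -1.42 to -1.25 in IMQ and -1.56 to -1.52 in CRS+IMQ libraries. The T cell mean was -0.73 to -0.70, -0.55 to -0.49 and -0.60 to -0.59 in the same order. Fibroblast genes had 20 of 25 positive (21 adjusted over the list alone) and eicosanoid genes 19 positive and 1 negative of 25 (20 and 1 adjusted over the list alone), with medians of 1.56 and 1.79 (adjusted p = 1.15e-07 and 3.22e-07, or 0.272 and 0.241 with an estimated correlation). The eicosanoid mean relative to control was -1.11 to -1.03 in CRS, -0.69 to -0.62 in IMQ and -0.22 to -0.18 in CRS+IMQ libraries. All of these group means thus lay below that of control. On the negative side were 8 of 9 melanocyte genes, 20 of 21 muscle genes and 25 of 31 hair follicle genes, 4 of which were positive (medians -2.66, -2.13 and -2.02, adjusted p = 3.37e-05, 1.28e-08 and 2.67e-08, or 0.272, 0.283 and 0.283 with an estimated correlation). Clock genes had 13 negative and 2 positive of 18 (median -1.35, adjusted p = 7.03e-05, or 0.241 with an estimated correlation), with Per1 at -1.78 (adjusted p = 0.00071, or 0.0684 with each stressed group as 1 sample). Proliferation genes had 15 negative of 32 (14 adjusted over the list alone; median -1.07, or -0.69 without IMQ replicate 2, adjusted p = 2.63e-05, or 0.516 with an estimated correlation). Nuclear respiratory chain genes had 28 negative of 31 and mitochondrially encoded genes 10 of 13 (medians -1.04 and -1.03, adjusted p = 2.83e-11 and 0.000466, or 0.272 and 0.427 with an estimated correlation), and quantile normalization ended the second call (-0.31). Glucocorticoid-induced genes had 10 positive and 8 negative of 27 (set adjusted p = 0.887), with Fkbp5 at -0.95 (adjusted p = 0.000868, or 0.0954 with each stressed group as 1 sample), Zbtb16 at -1.76 (adjusted p = 0.00192, or 0.0903 with each stressed group as 1 sample) and Tsc22d3 at -0.48 (adjusted p = 0.359), which passed without IMQ replicate 2 (-0.82). Sets not past the threshold were glycolysis (adjusted p = 0.887), adipocyte (0.795), erythroid (0.764), Schwann cell (0.543), immediate early (0.429), stress hormone (0.35), endothelial (0.275) and sebaceous (0.192), and the sebaceous set passed without IMQ replicate 2 (-0.52). The median and the mean differed in sign for the immediate early list (0.02 and -0.14) and glycolysis (-0.30 and 0.35), and 9 of 15 basal keratinocyte genes were positive and 2 negative (median 0.87).

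Of 14864 genes, 7325 were past limma's adjusted threshold for the interaction, 4172 positive and 3153 negative. The fit with each stressed group as 1 sample called 2417, 1912 positive and 505 negative, and 2404 of them were among the 7325. Without the third IMQ library as well, 1320 passed, 1200 positive and 120 negative. In the first of these fits 13 hair follicle, 8 clock, 5 melanocyte, 5 nuclear respiratory chain and 4 muscle genes were negative, 6 dendritic and 3 T cell genes were positive, and the proliferation, mitochondrially encoded and adipocyte genes did not pass singly. Krt27, Krt71, Msx2 and H2ac18 did not pass in that fit (adjusted p = 0.0710, 0.0659, 0.0561 and 0.281). The 10 largest positive differences were Cxcl13, Sprr1b, Sprr2i, Wfdc17, Sprr2h, Fcna, Sprr1a, Ifitm6, Sprr2g and Lyz2, and the 10 largest negative ones Krt28, Krt73, Krt25, Krt35, Krt71, Krt27, H2ac18, Shh, Msx2 and Pdk4. H2ac18 varied within groups, with 0, 50.3 and 75.1 FPKM in the IMQ libraries, and its difference was not past the threshold without 9 of the 12 libraries, each left out singly. The positive share of calls was 56.96 percent in the values as given and 43.2 percent with quantile normalization, which moved the median of all genes from 0.04 to -0.13. Across 13311 genes, which are not independent replicates, the stress effect without imiquimod and that with imiquimod had a Pearson r of -0.319 and a Spearman rho of -0.378.

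**Figure D4:**
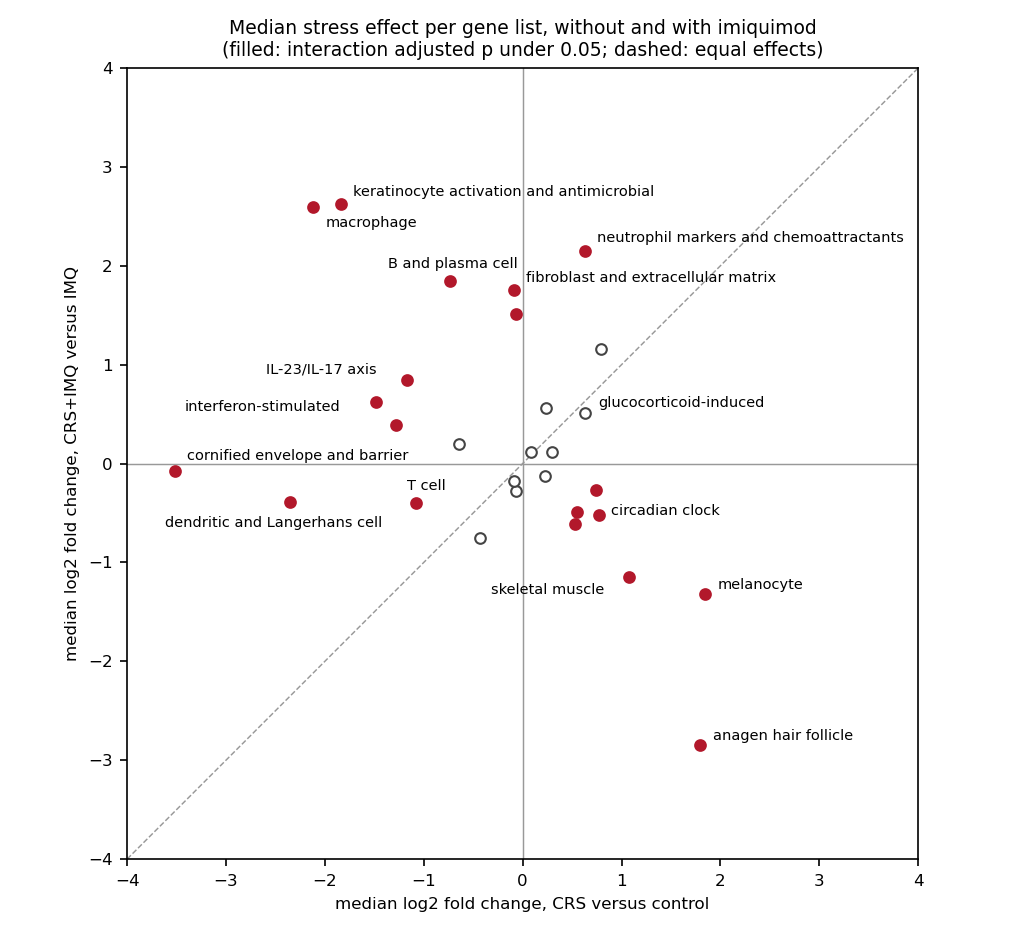
Median log2 fold change of each gene list in CRS versus control (horizontal) and CRS+IMQ versus IMQ (vertical), filled where the set passed in the interaction, with a dashed line where both effects would be equal. The macrophage list had medians of -2.12 and 2.60, and the anagen hair follicle list 1.80 and -2.84.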

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

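The tests of depth, of repeat libraries, of both explanations for the third IMQ library and of hair growth phase were chosen only after the results were seen. The test of the share of epidermis was set before its value was known, but it rests on a basal keratinocyte list added after the data were seen. Each of the following results drew attention because the effect of stress differed between skin with and without imiquimod, by a test of the interaction. The interaction was past the threshold for 7325 genes. Of the lists below, only the neutrophil, interferon-stimulated and B and plasma cell sets held in camera with an estimated correlation (adjusted p = 0.0342, 0.0139 and 0.0488). Neutrophil and B and plasma cell genes could enter that fit through the CRS+IMQ libraries alone, which favors positive differences. The median log2 difference of the stress effect was 1.85 for the IL-23/IL-17 axis, 3.57 for keratinocyte activation, 2.37 for the cornified envelope, 1.63 for neutrophil genes and 2.05 for interferon-stimulated genes. It was 0.88 for T cells, 4.77 for macrophages, 1.70 for dendritic cells, 1.60 for mast cells, 2.93 for B and plasma cells, 1.56 for fibroblasts and 1.79 for eicosanoid metabolism. It was -1.07 for proliferation, -1.35 for the clock, -2.13 for skeletal muscle, -2.02 for the hair follicle, -2.66 for melanocytes, -1.04 for nuclear respiratory chain genes and -1.03 for mitochondrially encoded genes. Among single genes it was 4.39 for Il1b, 4.52 for Il1f9, 2.78 for Krt6a, 5.68 for Krt16, 2.87 for S100a9 and 3.11 for Lcn2. It was -0.95 for Fkbp5, -1.76 for Zbtb16, -1.78 for Per1, 2.69 for Lor and 2.48 for Flg.

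Regrouping of the libraries gave too few divisions to judge the comparisons of 2 groups, with 10 each. In CRS versus control 1 of 10 divisions, the real one, reached 6086 genes and the highest other had 2. In CRS+IMQ versus IMQ 1 of 10 reached 5162 and the highest other had 1, in IMQ versus control 1 of 10 reached 5312 and the highest other had 6, and in CRS+IMQ versus CRS 1 of 10 reached 6718 and the highest other had 1. As many lists as in the real division were past the threshold in 3 of 10 divisions for CRS versus control (18 lists, highest other 18), 2 of 10 for CRS+IMQ versus IMQ (19, highest other 19) and 1 of 10 for IMQ versus control (21, highest other 18). The other divisions with the fewest lists still had 12, 10 and 13 past the threshold in the same order. Camera at the preset correlation thus called lists in every division tried. For the interaction 1 of 100 divisions reached 7325 genes and the highest other had 2225. Other divisions mix unlike groups, which widens the spread within them, and libraries of a stressed group may be repeats of the same RNA. The gene count therefore cannot argue against chance between animals. As many lists as the real 19 were reached in 6 of 100 divisions (highest other 20), and a correlation as large as -0.319 in 5 of 100 (highest other 0.352), so chance was not excluded for either.

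The libraries of the stressed groups resembled each other more than those of the other groups. The stressed groups had an estimated 1.01 times the fragments of the others. The depths searched spanned too narrow a range for this ratio to decide on the large excess that deeper sequencing predicted. For genes with at least 500 estimated fragments the spread argued against deeper sequencing. Their median coefficient of variation was 19.6 percent in control and 17.05 percent in IMQ. Counting noise at the estimated depths would give 2.47 and 2.53 percent, so most of that spread was not counting noise. Repeat libraries of the same RNA in each stressed group could account for a replicate SD of at most 0.0542 over 49 muscle, erythroid and adipocyte genes, against 0.525 in control and 0.214 in IMQ, but the IMQ value missed the bound set for that test. Animals made alike by the stress response would leave genes with little difference between CRS and control about as variable in both, but these had 0.571 times the SD in CRS (0.0688 against 0.120), short of what that explanation needs and not under the bound set against it. Repeat libraries and animals made alike both stayed open as explanations.

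IMQ replicate 3 lay between IMQ replicates 1 and 2. For 123 genes the weight of replicate 2 in replicate 3 had a median of 0.394 and an interquartile range of 0.160, against 0.759 to 0.918 for the control libraries and 0.847 and 1.24 for the IMQ libraries with replicate 1 or 2 as the middle, which is consistent with a mixture of the RNA of replicates 1 and 2. A separate animal at an intermediate stage was left undecided: the median weight of 4 lists spanned at most 0.0805 in 4 of the 8 selections of genes tried, and in the other 4 a list had under 3 genes, with a muscle median of 0.570 from 2 genes at a 2-fold minimum. If the third library was a mixture, IMQ had 2 independent samples.

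Epidermal differentiation transcripts were lower in CRS than in control. A smaller share of epidermis was left undecided. Basal keratinocyte genes stayed 2.87 above the cornified envelope genes in median log2 change, so these lists did not fall alike. Hair follicle genes rose in CRS, however, and whether follicles held up the basal list was not tested. Dilution by muscle RNA was argued against, as genes outside the muscle list had a median change of -0.0875. Hair growth phase was left undecided, with a difference in the cornified envelope mean of -0.222 between IMQ replicate 2 and replicate 1, against -3.08 in CRS relative to control. No test separated a direct effect of stress on keratinocytes from an effect by way of immune cells.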

How the results depend on the processing

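Every total of genes stayed within 1.5 times its value under quantile normalization, median-ratio scaling, no filter, a pseudocount of 0.1 and a fit of all 12 libraries. With a filter of 5 FPKM fewer genes were tested and 3954, 3406, 3453 and 4786 passed in CRS versus control, CRS+IMQ versus IMQ, IMQ versus control and the interaction. A 2-fold limit left 1711, 1469, 1417, 2037 and 3607 in CRS versus control, CRS+IMQ versus IMQ, IMQ versus control, CRS+IMQ versus CRS and the interaction, and an unadjusted p with 2-fold left in the same order 1745, 1535, 1454, 2068 and 3700. With each stressed group as 1 sample, and so fewer samples, 793, 820, 2725, 1111 and 2417 passed, and without the third IMQ library as well 304, 1229, 589 and 1320 in the last 4. In simulated data that fit found 0 percent of 2-fold and of 4-fold changes in CRS versus control, so genes it did not call are not shown to be unchanged. IMQ versus control had 2735 in a fit of its 2 groups. With an estimated correlation 0, 0, 1 and 3 lists passed in CRS versus control, CRS+IMQ versus IMQ, IMQ versus control and the interaction, and the cause was not tested. Directions reversed for mt-Co3 in CRS versus control (-0.15) and mt-Co1 in the interaction (0.20) under quantile normalization, and for glycolysis under fry in CRS versus control (median 0.30) and CRS+IMQ versus CRS (-0.36), and the cause was not tested. Calls of 7 sets ended under fry: skeletal muscle, erythroid and endothelial in CRS versus control (adjusted p = 0.0825, 0.116 and 0.353), proliferation in CRS+IMQ versus IMQ (adjusted p = 0.244) and the interaction (adjusted p = 0.0546), and nuclear respiratory chain and mitochondrially encoded genes in IMQ versus control (adjusted p = 0.0708 and 0.123). Another 16 sets passed under fry alone. With each library left out the totals of the 5 comparisons ranged from 4246 to 7127, 3427 (without CRS_IMQ replicate 2) to 6156, 4091 to 5866, 5739 to 5826 and 6631 to 7872, the lists (without CRS+IMQ versus CRS) from 17 to 19, 18 to 19, 18 to 21 and 19 to 20, and the correlation from -0.34 to -0.30. Of values for single genes 4925 stayed on their side of the threshold, 115 were weaker and 24 stronger. With a replicate block 4811, 3974, 4866, 6467 and 7062 genes passed, and libraries of the same number did not pair (correlations of 0.0353, -0.0354 and -0.127 in CRS versus control). Tests on counts were not run. Whether the estimated depth of 19.1 to 21.1 M fragments limited genes under 1 FPKM, among them Il17a, Il17f and Il23a, was not tested.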

Other observations

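No hypothesis was tested in this part. The fits of all 12 libraries gave CRS versus control and IMQ versus control changes that correlated across 14864 genes with r = 0.717. Both comparisons share the control libraries, and simulated data with no effect had r = 0.498, so part of the resemblance may come from the shared controls. The covariance was 0.333, against 0.0243 in the simulated data.

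The authors' deposited table called 3365 genes in CRS versus control and 3329 in CRS+IMQ versus IMQ. Of the calls in the authors' deposited table among genes tested here, 2426 of 2519 and 2142 of 2378 were also called here, all with the same sign. The deposited calls had a p-value under 0.05 and at least a 2-fold change, with q-values up to 0.123 and 0.134.

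Mitochondrial genes held 8.69 to 20.2 percent of the FPKM of a library, and the 10 highest genes 11.8 to 26.5 percent. The highest gene was mt-Co1 or Acta1, and Acta1 held 5.32 to 5.46 percent in the CRS libraries.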
